A study of Caenorhabditis elegans with 6 samples.

How the data were processed

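Poly(A)-selected RNA of whole C. elegans animals of the N2 strain was sequenced in 6 libraries, 3 from animals given aspartame (ASP) and 3 from controls (Control). The deposited table has 25212 genes on 6 nuclear chromosomes, of which 18596 are protein-coding and 13 are ribosomal RNA (rRNA) genes. It gives an FPKM value and a count per gene and library, per the file headers. The aligner, the counting tool and the use of strand are not given in the sources used here. The submitters' processing notes name CASAVA 1.4 and the mouse builds mm9 and mm10, but the chromosome accessions in the file are those of the C. elegans build WBcel235. Of the gene IDs, 25206 were found in the RefSeq gene table, with the same start for 97.1% and the same end for 96.1% of them. Coordinates are printed as the file gives them.

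The deposited FPKM values are scaled to transcript length and to sequencing depth, per the file headers. The deposited counts are estimated counts, already whole numbers, so rounding them changed nothing. Among short noncoding genes with counts under 30, between 98.3% and 99.0% per library lay 0 to 1 above the FPKM times the length times 1 constant (tolerance 0.02), as estimates rounded up would. Counts of 4 were held by 374 to 430 genes per library, against 249 to 367 genes with a count of 3 and 143 to 188 with a count of 5. A single fragment may thus be worth several counts, and no counting interval was derived from them. The table's unit was checked against its values before the choice between the tests named in the plan was made.

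Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 13790 in all. ASP was compared with Control by edgeR 4.0.16 (quasi-likelihood test, TMM normalization, R 4.3.3) on the counts, with Benjamini-Hochberg adjustment and a threshold of 0.05. The plan named limma on log2(FPKM + 1) unless the table also held raw counts. The table held estimated counts, which may not meet that condition, and edgeR on them gave the reported values. With limma on log2(FPKM + 1), 0 genes and 7 lists were called, against 0 genes and 8 lists. Fold changes are log2(ASP/Control) with a standard error (SE) from the edgeR fit. Gene lists with at least 3 tested members were tested by camera (limma 3.58.1) with a preset correlation between genes of 0.01, and adjusted over the 42 lists. Camera with the correlation estimated per list, and fry, served as alternatives. With an estimated correlation camera did not call even the molting genes in number 1 against numbers 2 and 3 (adjusted p 0.849), where 23 of 25 members passed. Its lack of a call is therefore weak evidence against a list. fry asks whether a list's own genes move, on balance, one way, or, in its mixed form, in either direction. The list of mitochondrial-genome genes had no tested member and was not analysed here. Where the names given for 1 list entry belonged to different genes, the gene whose symbol stands in the table was used, and 18 list entries were not in the table.

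The tests, the thresholds, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Whether counts or FPKM served the main test was settled once the contents of the table were known. Under that rule the text names up to 15 genes per direction that pass the threshold. Where fewer than 5 pass, it gives the 5 with the smallest p, said not to pass. From each list it gives the members that pass, up to 4, or it may give the 1 member with the smallest p. A set of 16 immune, stress and metabolic genes is always given (pmk-1, sek-1, nsy-1, sysm-1, irg-1, irg-4, irg-5, lys-7, clec-60, daf-16, sod-3, hsp-16.2, hsp-4, hsp-6, gst-4 and pah-1). Genes outside the rule are marked where they appear.

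The groups share the replicate numbers 1 to 3, so the fit with the replicate number as a block was planned as an alternative. Deviations from the group means correlated across genes within each number (0.769, 0.482 and 0.791 for numbers 1, 2 and 3). Each of the 6 libraries correlated best with the library of its own number in the other group. The numbers were therefore read as pairing the libraries. The planned main fit stayed without the block, so reported values do not use the pairing unless the block is named. The labels do not say what a number stands for. They also do not state separate cultures, so the p-values measure the spread between these libraries, which may be technical.

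Other alternatives were DESeq2 1.42.0, limma on FPKM with other pseudocounts, filters, scalings and weights, other edgeR normalization and filters, and each library left out in turn. The fits with 1 library left out had no block. The replicate number of that library then stood in 1 group only, so differences between numbers entered the comparison of ASP with Control. All 10 splits of the 6 libraries into groups of 3 were also fitted. The tests were run on simulated data with known answers, drawn from the means, spreads and library sizes of these libraries, with 200 of 13790 genes changed. Without the block, edgeR recovered 0% of genes changed 1.5-fold, 3% at 2-fold and 70.6% at 4-fold, with 0% false among the calls. With the block it recovered 60.6%, 87.5% and 98.9%, with 10.7%, 6.54% and 7.70% false. In 10 simulated draws camera called a list raised 1.5-fold, the lysozymes, in all 10, and in 10 draws with no list effect it called 1 list in total. Genes were drawn independently of each other, so these draws do not show how often camera calls lists of correlated genes. Other splits of the real libraries called up to 22 lists. Principal components were computed from log2 CPM (counts scaled to library size) with a prior count of 2. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The infection status of the sequenced animals is not given in the sources used here.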

Results

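The data are gene expression profiles of whole worms given 100 µM aspartame, the dipeptide sweetener made of aspartic acid and phenylalanine methyl ester, and of control worms. The series describes a test of innate immunity against Pseudomonas aeruginosa, but the labels do not say whether the sequenced animals had met the bacterium. Total counts were 53558562, 57702213 and 53926593 in ASP 1, 2 and 3, and 55254791, 55252845 and 63581942 in Control 1, 2 and 3. Between 19372 and 20215 genes had a count above 0. Genes for rRNA took 5.10%, 5.74% and 7.19% of the counts in ASP 1 to 3, and 3.24%, 5.81% and 5.26% in Control 1 to 3. FPKM values below are mean ± SD of the 3 libraries of a group.

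The comparison of ASP with Control asks which genes and pathways, immune genes above all, respond to aspartame. No gene passed the threshold in edgeR (0 of 13790), and 62 genes had an unadjusted p under 0.05, which is 0.450% of those tested. A share of 0.05, or 5%, is expected with no difference between the groups. Without the block, differences between replicate numbers counted as spread within a group, and with it the share was 2.68%. The lowest adjusted p in edgeR was 0.9999. The 5 genes higher in ASP with the smallest p did not pass. The cuticlin-like gene cutl-11 (188066, X 11648188 to 11650851) had 1.72 ± 0.347 FPKM in ASP and 0.963 ± 0.0746 in Control (log2 0.82, SE 0.24). The others were C14B9.13, a noncoding RNA (13190346, III 8109592 to 8109734, log2 1.49, SE 0.38), linc-18 (24104425, I 12215538 to 12216323, 1.65, SE 0.45), F46A8.11 (13182072, I 11248270 to 11250018, 1.0, SE 0.27) and C54G10.1 (183818, V 14641101 to 14641382, 1.17, SE 0.38). The 5 lower genes with the smallest p did not pass either. They were the ligand-gated channel gene lgc-25 (181525, X 14158785 to 14161734, log2 −0.87, SE 0.24), the insulin-like peptide gene ins-24 (173266, I 14031147 to 14031667, −0.97, SE 0.30), F26G1.2 (184993, II 4763081 to 4764180, −0.60, SE 0.19) and the histone genes his-56 (178055, IV 11338522 to 11338833, −0.92, SE 0.28) and his-46 (178050, IV 11326018 to 11326329, −0.95, SE 0.30). Histone genes have near-identical copies, so the values of single ones are uncertain. With the replicate number as a block, edgeR also called 0 genes, with 369 at an unadjusted p under 0.05. When the libraries numbered 3 were left out as well, a setting chosen after the data were seen, it called 39 (5 higher, 34 lower). That fit had only numbers 1 and 2 to measure spread with, and it was not run on simulated data. Its calls include T04C12.23, chosen after its values were seen. Of the libraries in the fit, this gene was above 0 in Control 2 alone (8.42 FPKM). DESeq2 called 0 genes with and without the block (242 and 73 at an unadjusted p under 0.05), and limma on FPKM called 0 (71, and 407 with the block). With array weights, limma called 0 genes, with 2135 at an unadjusted p under 0.05 and a lowest adjusted p of 0.154. The median 95% interval of a gene reached log2 0.49 to either side, or 1.4-fold, and 0.26 or 1.2-fold with the block. In data simulated at this spread, edgeR without the block recovered 0% of genes changed 1.5-fold and 3% of those changed 2-fold, and with the block 60.6% and 87.5%.

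Neither the p38 MAP kinase pathway of innate immunity nor the list of PMK-1-dependent and P. aeruginosa-response effectors was called. The effector list is thus not limited to genes that depend on p38. pmk-1, the p38 kinase itself (191743, IV 8148794 to 8151266), had 11.71 ± 1.66 FPKM in ASP and 9.32 ± 1.23 in Control, a log2 difference of 0.32 (SE 0.16, 95% interval −0.07 to 0.71) that did not pass. It was higher in ASP in each pair (log2 0.28, 0.02 and 0.63), and with the block the log2 difference was 0.31 (95% interval 0.01 to 0.61), with an adjusted p of 0.997 in edgeR. The upstream kinases had values close to 0, with log2 0.04 (SE 0.10) for sek-1 and −0.02 (SE 0.10) for nsy-1. In the effector list, log2 was −0.07 (SE 0.57) for sysm-1 (T24B8.5), 0.03 (SE 0.29) for irg-1, 0.04 (SE 0.46) for irg-4 and 0.14 (SE 0.37) for irg-5. The lysozyme gene lys-7 stood at −0.12 (SE 0.42) and the lectin gene clec-60 at 0.02 (SE 0.35). With the block, sysm-1 was at −0.07 (SE 0.14), irg-4 at 0.07 (SE 0.09) and lys-7 at −0.11 (SE 0.07), and none passed. The transcription factor gene zip-2 had the smallest p of the effector list, with 206.1 ± 21.7 FPKM in ASP and 225.8 ± 23.8 in Control.

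**Figure D1:**
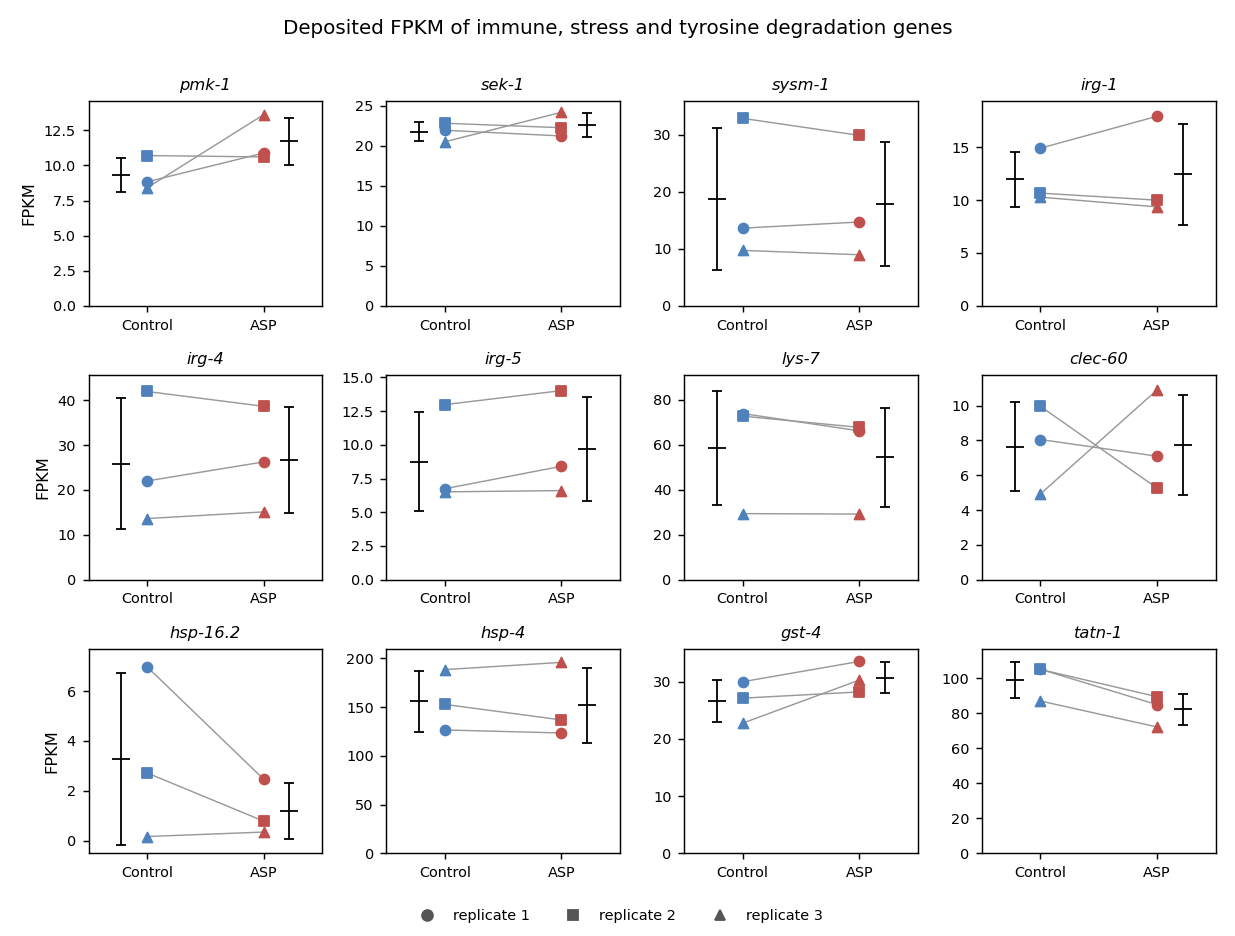
FPKM of 12 immune, stress and metabolic genes in each library, with ASP and Control side by side, lines joining libraries of the same replicate number, and black bars for the mean ± SD of 3 libraries. In sysm-1, irg-4 and lys-7 the replicate numbers lie farther apart than the groups, whose log2 differences are −0.07, 0.04 and −0.12.

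Of the 9 tested pathway components, 4 were higher and 5 lower in ASP (median log2 −0.00, with camera's direction upward, adjusted p 0.692), and limma on FPKM, with or without quantile normalization, gave a median above 0. Of 20 effectors, 8 were higher and 12 lower (median −0.04, adjusted p 0.870). This list turned with the libraries numbered 3, in fits without the block: camera called it higher without ASP 3 (0.18, adjusted p 0.0227) and lower without Control 3 (−0.20, adjusted p 0.0269). The CUB-like genes, 9 higher and 6 lower of 15, did the same (0.23, adjusted p 0.0123 without ASP 3, and −0.22, adjusted p 0.0490 without Control 3), were also called without Control 2 (0.30, adjusted p 0.00319), and had a median of 0.08 (adjusted p 0.806) with all libraries. C32H11.4 was the member with the smallest p (log2 0.28, SE 0.44). C-type lectins were 53 higher and 44 lower of 97 (median 0.01, adjusted p 0.698), called only without Control 2 (0.14, adjusted p 0.00126), and clec-137 had the smallest p (log2 1.93, SE 0.75). Lysozymes were 4 higher and 5 lower of 9 (median −0.05, above 0 in limma on FPKM under each scaling, camera's direction upward, adjusted p 0.806), with ilys-4 at 0.21 (SE 0.22). Their median was also above 0 with each library left out in turn (0.015 to 0.075). Saposin-like and antibacterial factor genes were 12 higher and 9 lower of 21 (median 0.01, adjusted p 0.692), with abf-2 at 0.93 (SE 0.41). The pals genes of the intracellular pathogen response were 10 higher and 2 lower of 12 (median 0.09, adjusted p 0.203, and 0.22 with adjusted p 0.00683 without Control 2), with pals-39 at 0.50 (SE 0.50).

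Caenacins and related antimicrobial peptide genes, which the epidermis makes on fungal infection or wounding, were the only immune list that camera called. They fell in ASP, with 12 of 13 members below 0 (median −0.17, adjusted p 0.0225, and adjusted p = 0.776 with an estimated correlation). nlp-31 had 21.3 ± 2.23 FPKM in ASP and 30.6 ± 10.8 in Control (log2 −0.55, SE 0.31). The pair medians were −0.04, −0.14 and −0.49. The call ended without ASP 3 (0.12, adjusted p 0.973), Control 2 (−0.09, adjusted p 0.129) or Control 3 (−0.28, adjusted p 0.121).

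Among the stress responses, heat shock and HSF-1 genes fell as a list, with 19 of 20 members lower in ASP (median −0.24, adjusted p 3.71e-05, and adjusted p = 0.776 with an estimated correlation). No member passed alone with all libraries. The small heat shock protein gene hsp-16.2 (V 1804334 to 1804957) had 1.202 ± 1.12 FPKM in ASP and 3.29 ± 3.44 in Control (log2 −1.43, SE 1.16). Its neighbour hsp-16.41 had 1.19 ± 1.44 and 3.60 ± 3.27 (log2 −1.60, SE 1.28). The medians of the list were −0.41 in pair 1, −0.34 in pair 2 and 0.15 in pair 3. Molting and cuticle genes had medians of the same signs, −0.41, −0.30 and 0.28, with 19, 22 and 5 of 25 lower in ASP. Heat shock genes were also lower in the libraries numbered 3 of either group, with 12 of 20 passing and a median of −1.12 against numbers 1 and 2 (adjusted p = 0.772 with an estimated correlation). The call in ASP against Control ended without ASP 3 (−0.18, adjusted p 0.268), Control 1 (−0.20, adjusted p 0.294) or Control 2 (−0.21, adjusted p 0.0951). It stayed, with medians farther below 0, without Control 3 (−0.54), ASP 1 (−0.49) or ASP 2 (−0.38). These fits had no block, and heat shock genes were also higher in number 1 than in numbers 2 and 3 (median 0.82). Leaving out a library numbered 1 or 3 would move the median in these directions with no effect of aspartame. The fits thus do not show how firm the call is.

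The unfolded protein responses were not called, with 4 members higher and 15 lower of 19 for the endoplasmic reticulum (median −0.03, adjusted p 0.633) and 8 higher and 4 lower of 12 for mitochondria (0.04, adjusted p 0.633). Without ASP 3 the former was called lower (−0.12, adjusted p 0.0104). Their chaperone genes stood at log2 −0.06 (SE 0.25) for hsp-4 and 0.04 (SE 0.10) for hsp-6, and the smallest p belonged to dnj-7 (0.18, SE 0.14) and lonp-1 (0.09, SE 0.08). SKN-1 and oxidative stress genes were 13 higher and 11 lower of 24 (median 0.02, below 0 with median-of-ratios scaling, camera's direction downward, adjusted p 0.907), and their reporter gst-4 had 30.7 ± 2.68 FPKM in ASP and 26.6 ± 3.65 in Control. Insulin and DAF-16 genes were 14 higher and 9 lower of 23 (median 0.03, adjusted p 0.692), with log2 0.08 (SE 0.10) for daf-16, 0.16 (SE 0.22) for sod-3 and 1.298 (SE 0.58) for dod-3. Hypoxia genes were 4 higher and 6 lower of 10 (median −0.02, adjusted p 0.633, and −0.11 with adjusted p 0.0414 without ASP 3), with hif-1 at −0.04 (SE 0.08). Autophagy and lysosome genes were 7 higher and 17 lower of 24 (median −0.03, adjusted p 0.524).

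The UDP-glucuronosyltransferases, enzymes that attach sugars to foreign and endogenous small molecules, were the only list called higher in ASP. Of 50 members, 42 were above 0 (median 0.15, adjusted p 3.71e-05, and adjusted p = 0.776 with an estimated correlation), and the pair medians were 0.06, 0.11 and 0.27. ugt-17 had 14.0 ± 3.50 FPKM in ASP and 9.59 ± 0.397 in Control (log2 0.53, SE 0.22). ugt-3 (191174, V 12798308 to 12800271), chosen after its values were seen, was higher in ASP in each pair (log2 0.87, 1.78 and 0.64), with a blocked log2 of 1.18 (SE 0.21, adjusted p 0.997 in edgeR). In pair 1 it had only 0.519 FPKM in ASP 1 and 0.271 in Control 1. The call ended without ASP 2 (0.10, adjusted p 0.0972) or Control 3 (0.11, adjusted p 0.0685). The other detoxification families were not called. Cytochrome P450s were 23 higher and 14 lower of 37 (median 0.03, adjusted p 0.692, and 0.12 with adjusted p 0.0270 without ASP 1), with cyp-33E3 at 0.38 (SE 0.28). Glutathione S-transferases were 24 higher and 12 lower of 36 (0.03, adjusted p 0.955), with gst-43 at 0.30 (SE 0.19). P-glycoproteins and ABC transporters were 15 higher and 10 lower of 25 (0.03, adjusted p 0.633), with pgp-3 at 0.14 (SE 0.16).

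Genes for the breakdown of phenylalanine, aspartate and methanol, the products of aspartame digestion, were not called. tatn-1, the tyrosine aminotransferase (181574, X 14791008 to 14792984), had 82.2 ± 8.95 FPKM in ASP and 99.1 ± 10.4 in Control (log2 −0.29, SE 0.10) and was lower in each pair (−0.33, −0.20 and −0.34). Over all lists, 0 members passed when adjusted over the list alone without the block, and 2 with it, tatn-1 (log2 −0.29, SE 0.07) and ugt-3. This adjustment does not count the 42 lists tried, and over all genes both had an adjusted p of 0.997 in the blocked edgeR fit. The phenylalanine hydroxylase pah-1 had 50.9 ± 3.94 and 53.6 ± 16.07 FPKM. Phenylalanine and tyrosine genes were 3 higher and 5 lower of 8 (median −0.05, adjusted p 0.209, and −0.14 with adjusted p 0.0428 without Control 3). Aspartate and asparagine genes were 3 higher and 9 lower of 12 (−0.07, adjusted p 0.222), called without ASP 3 (−0.13, adjusted p 0.0397) or Control 2 (−0.10, adjusted p 0.00683), with mdh-1 at −0.12 (SE 0.10). Methionine, one-carbon and formaldehyde genes were 5 higher and 12 lower of 17 (−0.06, adjusted p 0.209), with the formaldehyde-oxidizing enzyme adh-5 at −0.13 (SE 0.09).

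Glycolysis and gluconeogenesis genes fell as a list, by a small amount, with 18 of 23 lower (median −0.05, adjusted p 0.00944, and adjusted p = 0.776 with an estimated correlation). ldh-1, lactate dehydrogenase, was at log2 −0.19 (SE 0.12). The call ended without ASP 2 (−0.03, adjusted p 0.196), ASP 3 (−0.10, adjusted p 0.116) or Control 1 (−0.03, adjusted p 0.660). Fatty acid synthesis genes were 10 higher and 13 lower of 23 (−0.01, adjusted p 0.806), with fat-6 at −0.10 (SE 0.14), and beta-oxidation and lipolysis genes were 11 higher and 14 lower of 25 (−0.00, adjusted p 0.882), with lipl-1 at 0.62 (SE 0.61). Their mean log2 lay above 0, camera's direction was downward, and both medians were above 0 in limma on FPKM, with or without quantile normalization.

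Sperm, ribosomal protein, collagen and germ line lists were called lower in ASP, each by under 0.13 in log2. The pair medians of the sperm, ribosomal protein and collagen lists differed in sign. Sperm genes were lower for 50 of 57 members (median −0.08, adjusted p 3.71e-05, and adjusted p = 0.938 with an estimated correlation), with pair medians of 0.04, 0.18 and −0.55. Cytosolic ribosomal protein genes were lower for 68 of 81 (−0.07, adjusted p 0.000226, and adjusted p = 0.938 with an estimated correlation), with pair medians of −0.11, 0.15 and −0.24. Collagens were lower for 105 of 115 (−0.12, adjusted p 0.00168, and adjusted p = 0.776 with an estimated correlation), with pair medians of −0.07, 0.09 and −0.30. Germ line genes were lower for 18 of 21 (−0.07, adjusted p 0.0357, and adjusted p = 0.776 with an estimated correlation). Without Control 3, the medians were −0.04 for sperm (adjusted p 0.764), 0.03 for ribosomal proteins (adjusted p 0.367) and 0.21 for collagens (adjusted p 0.581). The sperm call also ended without ASP 3 (0.06, adjusted p 0.120), and the ribosomal and collagen calls without ASP 1 (−0.02, adjusted p 0.679, and −0.03, adjusted p 0.305). The germ line call ended without ASP 2 (−0.09, adjusted p 0.0627), ASP 3 (−0.01, adjusted p 0.903) or Control 1 (−0.00, adjusted p 0.882).

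The replicate block changed the call for 3 further stage lists, each then called lower in ASP, though none of them was lower in every pair. The pair medians were −0.12, 0.03 and −0.33 for oocyte and eggshell genes, −0.33, 0.14 and −0.16 for vitellogenins, and −0.41, −0.30 and 0.28 for molting genes. In the libraries numbered 3 of either group, the medians of these lists differed from numbers 1 and 2 by −0.998 for oocyte and eggshell genes, −1.44 for vitellogenins and 1.74 for molting and cuticle genes. Oocyte and eggshell genes, 1 higher and 13 lower of 14, had a median of −0.10 (adjusted p 0.0993), and −0.14 with the block (adjusted p 7.1e-05, and adjusted p = 0.880 with an estimated correlation). Vitellogenins, the yolk protein genes, were lower for 6 of 6 (−0.10, adjusted p 0.633), and −0.11 with the block (adjusted p 0.04996, and adjusted p = 0.880 with an estimated correlation). Molting and cuticle genes were 17 higher and 8 lower of 25 (0.05, below 0 in limma on FPKM under each scaling, camera's direction downward, adjusted p 0.789), and −0.10 with the block (adjusted p 0.00657, and adjusted p = 0.880 with an estimated correlation). In fits without the block, these 3 lists changed direction with the library left out, from −0.40 without ASP 1 to 0.19 without ASP 3 for oocyte genes (adjusted p 9.09e-06 and 0.0198), from −0.44 without Control 3 to 0.24 without ASP 3 for vitellogenins (0.00184 and 0.0414), and from 0.60 without Control 3 to −0.88 without ASP 3 for molting genes (0.00293 and 3.08e-11). Such fits leave 1 number in 1 group only, so they also hold the differences between numbers given above. Molting genes were also called without ASP 1 (0.48, adjusted p 8.47e-06) and Control 1 (−0.28, adjusted p 9.86e-06), oocyte genes without ASP 2 (−0.14, adjusted p 0.0267) and Control 3 (−0.35, adjusted p 0.000116), and vitellogenins without ASP 2 (−0.39, adjusted p 0.0120).

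Markers of somatic tissues and of the embryo gave no call with all libraries. The medians were 0.02 for intestine (adjusted p 0.399), −0.05 for body wall muscle (0.513), −0.15 for pharynx (0.211), 0.02 for neurons (0.907), 0.02 for hypodermis (0.806, camera's direction downward), 0.07 for the 4 embryo genes (0.633) and −0.06 for the 4 coelomocyte genes (0.699), and those of muscle, neurons and hypodermis changed sign under at least 1 other scaling. Muscle and pharynx were called lower without Control 2 (−0.14, adjusted p 0.00283, and −0.25, adjusted p 0.00215), and hypodermis without ASP 3 (−0.51, adjusted p 0.0155). Histones, mostly without a poly(A) tail, had a median of 0.01 with camera's direction downward (adjusted p 0.0796), and below 0 with median-of-ratios scaling or quantile normalization. They were called lower without ASP 3 (−0.20, adjusted p 0.00355), Control 1 (−0.14, adjusted p 0.000254) or Control 2 (−0.05, adjusted p 0.0249). FMRFamide-like peptides had a median of −0.01, above 0 in limma on FPKM (adjusted p 0.633, and −0.10 with adjusted p 0.0296 without Control 2), with flp-17 at 0.32 (SE 0.18). Insulin-like peptides had a median of 0.05 with camera's direction downward (adjusted p 0.692).

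**Figure D2:**
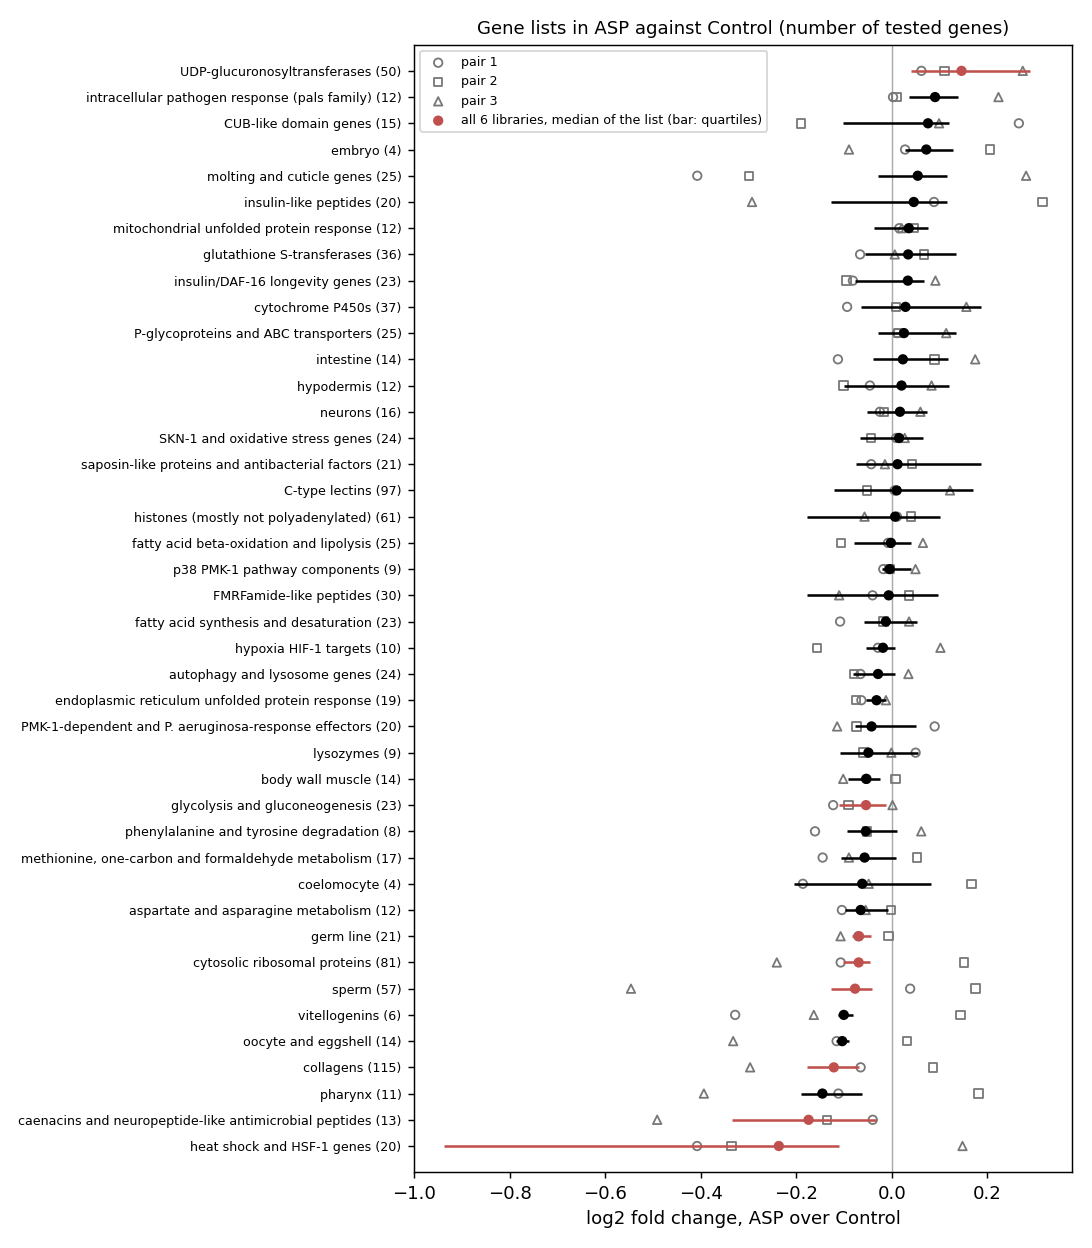
Median log2(ASP/Control) of each of the 42 lists, with bars for the quartiles of its members, open symbols for the medians of the 3 same-numbered pairs, and red for lists that camera called with the preset correlation. UDP-glucuronosyltransferases at 0.15 are the 1 list called higher, and 7 lists from −0.24 to −0.05 are called lower, with 0 lists called with an estimated correlation.

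With quantile-normalized FPKM, the UDP-glucuronosyltransferases stayed called (median 0.10, adjusted p 0.00476) and the other 7 lists did not, with the heat shock list at adjusted p 0.0573. Without the 2 libraries numbered 3, camera no longer called the caenacins, collagens, ribosomal proteins and germ line genes, and called the sperm genes higher (median 0.10).

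The libraries grouped by replicate number rather than by treatment. The principal component that held most of the variance, 67.5%, placed ASP 1 and Control 1 at −39.6 and −39.5, ASP 2 and Control 2 at −11.8 and −10.6, and ASP 3 and Control 3 at 53.01 and 48.5. In an edgeR fit with group and replicate number, a joint test for any difference between the numbers called 4579 of 13790 genes. The single contrast of number 3 against number 1 called 2527 genes higher and 2640 lower. The biological coefficient of variation was 29.3% without the block and 12.4% with it.

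**Figure D3:**
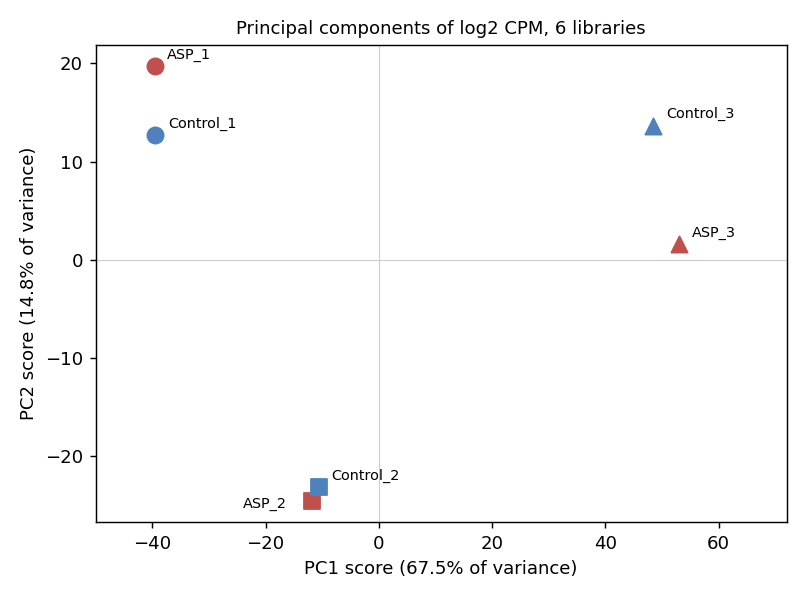
Scores of the 6 libraries on the principal components that hold 67.5% and 14.8% of the variance of log2 CPM, with ASP and Control in different colours and each point named. Libraries of the same number lie close together on the horizontal axis, at −39.6 and −39.5, −11.8 and −10.6, and 53.01 and 48.5.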

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

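The alternatives with rRNA genes left out, DESeq2 with the block, the block with an estimated correlation, and both libraries numbered 3 left out were chosen after the data were seen. The count of 0 genes held in each setting run for it (0 to 0 with each library left out in turn) except that edgeR called 39 genes (5 higher, 34 lower) without the libraries numbered 3 and with the replicate block. Of the 8 lists called, 1 remained with quantile normalization, the UDP-glucuronosyltransferases, and 0 with fry, 0 with an estimated correlation and 0 with the block and an estimated correlation. With each library left out in turn, 7 to 14 lists were called. The replicate block gave 0 genes and 11 lists, and beyond the oocyte, vitellogenin and molting lists, and tatn-1 and ugt-3 when adjusted over the list alone, it changed no other call by edgeR or preset camera. fry's mixed test with the block called 1 list, the FMRFamide-like peptides.

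For the 63 genes named by the rule, 1791 values kept their side of the threshold and 2 came past it: clec-137 (2.12) and hsp-16.41 (−2.09), both without number 3 and with the block. Of the genes named after their values were seen, which are outside these numbers, ugt-3 (1.66), hsp-70 (−1.27), F44E5.4 (−1.07) and noah-1 (−0.53) passed there too. For lists the numbers were 772 kept, 30 newly called, 56 lost and 23 reversed, and 194 sign changes over genes and lists, with neither setting called, count as kept. Reversed medians were −0.045 for histones at a mean count of at least 100, and −0.10 for molting genes with the replicate block. Without number 3, and then also with the block, they were −0.28 and −0.31 for molting genes, 0.10 and 0.10 for sperm, and 0.022 and 0.021 for ribosomal proteins. The block with number 3 left out gave −0.11 for hypodermis. With each library left out in turn, medians ran from −0.38 to 0.12 for caenacins, −0.26 to 0.21 for collagens, −0.23 to 0.30 for CUB-like genes, −0.13 to 0.026 for ribosomal proteins, −0.20 to 0.12 for histones, −0.51 to 0.42 for hypodermis, −0.88 to 0.60 for molting genes, −0.40 to 0.22 for oocyte genes, −0.20 to 0.24 for effectors, −0.18 to 0.060 for sperm and −0.44 to 0.24 for vitellogenins. The fits with 1 library left out had no block, so they also held the difference between the number left out and the others. Molting genes, higher by 1.74 in number 3, stood at −0.88 without ASP 3 and 0.60 without Control 3. How much of each shift this makes was not tested. In simulated data edgeR recovered 70.6% of single genes changed 4-fold without the block, and 60.6% of those changed 1.5-fold with it.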

Other observations

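Between replicate numbers, with group in the model, the libraries numbered 3 had 2616 genes higher and 2621 lower than the mean of numbers 1 and 2 in edgeR. Molting and cuticle genes were higher for 24 of 25 members (median log2 1.74), with mlt-10 at 1.91 (SE 0.07), and hypodermis markers for 9 of 12 (1.24, 3 lower). Oocyte and eggshell genes were lower for 13 of 14 (median −0.998) and vitellogenins for 6 of 6 (−1.44). Of the immune lists 3 were called lower, with 12 of 15 CUB-like genes (−0.71), 13 of 20 p38 and P. aeruginosa effectors (−0.75, 2 higher) and 34 of 97 C-type lectins (16 higher) passing, while saposins, caenacins, lysozymes, pals genes and p38 pathway components were not called. Camera called the lectins lower in number 3 against number 2 (−0.34, adjusted p 1.76e-05) but not against number 1 (−0.06, adjusted p 0.205). irg-6 was lower by log2 −4.26 (SE 0.20). The fatty acid and retinol binding gene far-3 was higher by 4.92 (SE 0.12), at 517.0 and 552.9 FPKM in ASP 3 and Control 3 and from 8.74 to 45.7 in the other 4 libraries. Number 1 stood apart too: against numbers 2 and 3, molting genes were lower for 23 of 25 (−1.74) and oocyte genes higher for 13 of 14 (0.86), and in number 2 against number 1 molting genes were higher for 19 of 25 (1.09). camera called these lists with the preset correlation and none with an estimated one (adjusted p = 0.658 to 0.849 with an estimated correlation). These genes were chosen after their values were seen.

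The libraries numbered 1 differed from numbers 2 and 3 in the propionate shunt, the route that breaks down propionate when vitamin B12 is short. The 5 genes of it examined were higher: acdh-1 by log2 6.92 (SE 0.12, 349.7 and 363.6 FPKM against 1.43 to 4.80), hphd-1 by 2.29 (SE 0.07), ech-6 by 1.41 (SE 0.07), hach-1 by 1.09 (SE 0.07) and alh-8 by 0.61 (SE 0.08). The folate transporter gene folt-2 was higher by 1.98 (SE 0.07). The methionine synthase gene metr-1, whose enzyme uses B12, and the gene of its reductase, mtrr-1, were higher by 0.26 (SE 0.07) and 0.31 (SE 0.08), and mthf-1, ahcy-1, sams-1 and mel-32 of the same cycle were not called. Taken singly in edgeR, number 1 differed in metr-1 from number 2 (adjusted p 0.0386) but not from number 3 (0.362). In mtrr-1 it differed from neither (0.0816 and 0.0883). Of the B12-dependent propionate pathway, pcca-1, pccb-1, mmcm-1 and mce-1 were not called. ugt-3, which was higher in ASP in each pair, was lower in number 1 by log2 −6.32 (SE 0.31). The genes and sets of this paragraph were chosen after their values were seen.

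All tests below were chosen after the results were seen. The split by replicate number is the strongest structure in these libraries, and no biological explanation from the study's groups was tested for it. Sequencing depth is argued against, since ASP 1 and ASP 3 lay 100% of the range of the main component apart with totals that differ by 0.3 M counts (53.6 M and 53.9 M). rRNA left in the library is argued against in the same way, since ASP 1 and Control 3 lay 95.1% of the range apart with rRNA shares that differ by 0.156 percentage points. Animals at different stages may account for it, as 24 of 25 molting genes were higher and oocyte, eggshell and yolk genes lower in number 3. Molting medians rose from number 1 to 2 (1.09) and from 2 to 3 (0.99), and oocyte medians fell in both steps (−0.45 and −0.77). Differences in stage could give such an order, though yolk genes fell only from number 2 to 3 (0.01, then −1.39). Whether the numbers also mark a batch, a food source or a culture stays open.

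Whether the 8 lists called in ASP against Control owe their calls to correlation between the genes of a list stays open. With the correlation estimated per list camera called 0 lists, but it also called 0 in the split with 22 preset calls. For molting genes in number 1 against numbers 2 and 3, where 23 of 25 passed, it gave adjusted p 0.849. Its lack of a call thus cannot decide. The 10 splits of the 6 libraries are too few for a share under 0.05: the real split called 8 lists, the highest other split 22, and 6 of the 10 splits called at least as many. The split with 22 keeps same-numbered libraries together in 2 pairs and points to a structure of the libraries, while the 3 other splits that part all 3 pairs called 9, 5 and 5 lists, or 18, 13 and 10 with the block against 11 for the real split. For genes in edgeR without the block, the real split gave 0 (62 at an unadjusted p under 0.05) and the highest other 0. With 0 genes in the real split, every split gives at least as many, so this comparison cannot decide. With the block, the 3 other splits that part all 3 pairs gave 2, 0 and 0 genes, against 0 for the real split. At an unadjusted p under 0.05 in edgeR they gave 885, 1060 and 346 genes, against 369. An effect of aspartame on single lists stays open, as untested beyond these calls.

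Heat shock genes were lower in ASP in pairs 1 and 2, for 19 and 17 of 20 members (medians −0.41 and −0.34), and higher for 11 of 20 in pair 3 (0.15). Without number 3 and with the block, 8 of the 39 genes called were heat shock genes and 6 were molting and cuticle genes, all lower, among them, chosen after their values were seen, hsp-70 (log2 −1.27), F44E5.4 (−1.07), which has a near-identical copy, and noah-1 (−0.53). Several of the 8 heat shock genes had near-equal values in every library, as F44E5.4 and its copy did, so they are not 8 separate signals. The fit that called them had only numbers 1 and 2 to measure spread with. Heat shock and molting medians had the same sign in 3 of 3 pairs and opposite signs between number 3 and the other numbers, which goes against that stage difference within pairs, but it stays open because the heat shock list was not called between numbers 2 and 1. Labels exchanged between the libraries numbered 3 could give the reversal but cannot be told apart from it: of the 38 called genes measured above 0 in both groups, 11 moved the same way in pair 3, and with the exchange 2 genes were called with the block against 0. A response to aspartame that differs between the pairs stays open, as untested.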
